A study of Mus musculus with 6 samples.

How the data were processed

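Total RNA of 6 samples of ID8agg cells was sequenced, 3 with a control hairpin and 3 with a hairpin against Msln, per the labels. The submitters' processing notes name fastp, HISAT and RSEM, and the genome build GRCm39, without versions. How each tool was used, and the annotation release, are not given in the sources used here. The table deposited by the authors is named as a count matrix, but its sample columns hold TPM, a normalized unit of transcript abundance: this was judged from their decimals and column totals when the unit was identified. TPM values keep no sequencing depth.

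Samples were grouped from their titles. Columns were to be matched to samples only by name. A column assigned by its Msln values would leave those values unable to check the labels. For other genes it would set only the direction. All 6 numbered sample columns matched no label, and they were left out, with the columns holding their means. The test fixed before the data were examined for a table without counts was limma on log2 values with group as its only term, followed by tests of gene lists and of annotation terms. None of these tests was run. A test between the 2 sets of column names, without saying which is the knockdown, was feasible and was not run either, under the same rule on column names.

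What was computed rests on the annotation columns of the table and on its length column, which holds 1 value per gene. Genes, symbols and annotation were tallied with Python 3.11.15 and pandas 2.3.3. A total of 43792 genes carried a GO term and 8585 a KEGG pathway. Of 346 pathways named, 316 were mentioned 15 to 300 times over the listed genes. Repeated mentions within a gene, if any, were not removed. The test of terms set the same limits on tested genes, so the number of terms it would have used is not known. The members of 36 gene lists were matched to the table by exact symbol. The reference name table, of build GRCm38, was used for names only, and no coordinate was taken from it. The rule for named genes kept Msln, Muc16 and Cd274 always, and its other parts need a test and named no gene. Genes given as missing from a list were named after the match was seen.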

Results

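The study measured gene expression by RNA sequencing in ID8agg cells, a line derived from ID8, a mouse ovarian surface epithelial cancer line. The labels place the 6 samples in 2 groups. In 3 samples the cells carried a control short hairpin RNA, and in the other 3 a hairpin against Msln, the same one in each by the labels. Msln encodes mesothelin, a cell-surface protein of mesothelium and of many ovarian cancers. The comparison that this design implies, knockdown against control, asks which transcripts differ in the cultured tumour cells that carry the hairpin against Msln. It cannot tell loss of Msln from other effects of that hairpin.

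No result of that comparison is given here. The table of the series holds 6 numbered sample columns under the names Positive and Negative, and all 6 names match no label of any sample. Either name can be read as either group, since Negative can stand for a negative-control hairpin or for cells negative for mesothelin. A direction could therefore be set only by guessing or by looking at the expression values themselves, and neither was done. The table would allow a test of the columns named Positive against those named Negative with the direction left open. That test was not made, because a column was used only where its name matched a sample. The values were read only to identify their unit, and none entered a comparison, so no gene is described as higher or lower in either group. The values of Msln were not examined. The depth of the libraries is unknown, because the deposited values were already normalized.

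The table listed 56980 mouse genes by Ensembl identifier, and 55438 of them carried a symbol. Msln was listed as ENSMUSG00000063011, with a length of 2114 bases. Whether the listed lengths count transcript bases or the genomic span of a gene is not stated. Muc16, which encodes the mucin that binds mesothelin, was listed as ENSMUSG00000109564 with 25437 bases. Cd274, which encodes the immune checkpoint ligand PD-L1, was listed as ENSMUSG00000016496 with 3622 bases. The median length over all listed genes was 1067 bases. The coordinates of these genes are not given, because the annotation at hand belongs to another genome build than the one the submitters name.

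Of 1145 genes in 36 lists fixed before the data were examined, 1128 were found by symbol. The lists covered antigen presentation, interferon response, chemokines, cytokines, checkpoint ligands, adhesion, matrix, proliferation, stress, metabolism and signalling, and markers of cell types that the culture should not hold. All 27 genes of MHC class I antigen presentation, all 32 chemokines, all 55 cytokines and growth factors and all 28 markers of mesothelium and ovarian surface epithelium were listed. Of the 37 checkpoint ligands and immunosuppressive factors, 36 were listed, Hhla2 being the exception. The type I interferon list had 49 of its 50 symbols in the table, which did not list Rigi but did list Ddx58, the older symbol of the same gene, as ENSMUSG00000040296. In the respiratory chain list 47 of 53 symbols were found, and the 6 others were symbols of ATP synthase subunits such as Atp5f1a. In the list of replication-dependent histones 38 of 47 symbols were found, and the 9 others were older symbols such as Hist1h1c. These numbers say which symbols the table lists, not whether the genes were expressed. A gene whose symbol was not found can be listed under another symbol, as Rigi was, or not be listed at all. Which of these holds for Hhla2 was not determined.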

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

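The number of list genes found in the table was 1128 with exact symbols and again 1128 when case was ignored. It was 1137 when symbols were also matched through the Ensembl identifiers of the reference name table. Both alternatives were chosen after seeing the data. The alternatives planned for the comparison of knockdown with control (normalization, filter on low values, tool, threshold, left-out replicates and replicate block) were not run, because columns whose names match no sample were left out. The table itself would allow them between the 2 sets of column names, with the direction open. Under that rule on column names no paired analysis was possible because no column matched a sample. A fit with the column number as a block was therefore not run, though the table has the columns for it, and whether those numbers are the replicate numbers of the labels is not known.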
